A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

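The 14 samples are pooled CRISPR screens with hgRNA libraries in HAP1, RPE1, CGR8 and N2A cells, sequenced as amplicons of the guide pair from genomic DNA. Per the submitters' processing notes, guides were matched with Bowtie 0.12.1, and the values are the count of reads per hgRNA as deposited in 1 table for each screen, with no normalization seen in them. Per the file headers, 2 of the tables hold a score of each Cas12a guide computed by the authors, which was not used, and how it was made is not given in the sources used here. The read length, mismatch settings and sequencing runs are not given in the sources used here. Per the labels' protocols, thymidine was used at 2.5 mM, 6-thioguanine at 6 uM and Torin1 at a dose that lowered growth by 60%. The 102 count columns of the listed samples were used, and 7 columns of plasmid or ligation libraries belong to no listed sample and were left out. The human table lists 127 entries without a guide, which were left out, and the exon deletion library lists 96 guide pairs more than once. Per the labels, replicates A, B and C come from one infection, so no p-value measures the spread between infections. The edgeR and DESeq2 tests, limma on gene means or replicate scores and the exact permutations of replicates measure the spread between these cultures. The other tests take hgRNAs, guides, genes or exons as units and do not measure that spread.

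hgRNAs were grouped by the annotation deposited with the counts: exonic Cas9 guide with an intergenic Cas12a guide, the reverse, guides on both sides of an exon, 1 guide beside an exon with an intergenic partner, both guides in 1 gene, guides in 2 paralogs, and both guides intergenic. The last class is the background (985 hgRNAs in the human optimization library, 994 in the mouse library, 1647 in the exon deletion library and 4993 in the dual-targeting library). Human exon positions match GRCh38 gene spans (99.49% of loci lay inside the span of their gene), but of the exonic Cas9 sites of the TKOv3 set in the exon deletion library only 13.61% did, for a reason not tested, and their positions were not used, and the mouse build is not given in the sources used here.

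Library factors were trimmed means of M-values (TMM) over the intergenic pairs only, since most of the libraries target fitness genes. hgRNAs with fewer than 30 counts at T0 were left out. Each hgRNA was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with a prior count of 2 for log2 fold changes and Benjamini-Hochberg adjustment at a threshold of 0.05. Each screen has 1 T0 library, which is assumed to vary as the replicates do. A gene or exon with at least 3 hgRNAs was tested by a two-sided exact rank-sum test of its log2 fold changes against those of the intergenic pairs, adjusted within its class of hgRNAs. This test treats hgRNAs, not cultures, as its units. Flanking pairs of an exon that share a guide are not independent, which the test does not allow for. Its p-values for exons may thus be too small and its counts of called exons too high. Torin1 against untreated cultures at T18, and HAP1 against RPE1 at their last time points, were tested with limma 3.58.1 on the mean over a gene's dual-targeting hgRNAs in each culture. Cas12a enzymes, and dual against single targeting, were compared by two-sided sign-flip permutation tests over genes (100000 permutations). Paralog pairs were scored as the log2 fold change of a pair minus the sum of its guides paired with intergenic guides, averaged per Cas9 guide and tested with the moderated test of limma (at least 3 Cas9 guides). Exons and single-guide hgRNAs were also compared by permutation and by Fisher's exact test.

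The 23 gene lists, 90 paralog pairs, the rule for naming genes and most of these tests were chosen before the data were examined. The permutation and Fisher tests of exons and single-guide hgRNAs were not in that plan, and those of exons followed the exon calls. The rule takes, for each test, the 10 items with the largest change in each direction among those past the threshold with the same sign in all 3 replicates, the drug targets HPRT1 and TK1, and the 4 members of each list with the smallest adjusted p. Alternatives were TMM over all hgRNAs, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no T0 minimum or one of 100 counts, an earlier time point, a block for replicate, leaving out each replicate, other backgrounds and other forms of the pair score. Added after seeing the data were T0 as the reference for drug selections, HAP1 and RPE1 both at T18, a moderated test over the hgRNAs of a gene, single Cas12a guides as the only single-guide reference, p-values of paralog pairs from 100 simulated additive screens, the direct comparison of Cas12a enzymes in mouse cells and a test of exons on the X chromosome.

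The main tests were tried on simulated data, but the permutation and Fisher tests, the Torin1 test over hgRNAs and the pair scores outside untreated HAP1 were not. In simulated counts of the human optimization library, edgeR called 72.3% of hgRNAs changed by -4 and 7.74% of those changed by -2, and 8 of 85949 unchanged hgRNAs, while DESeq2 called 254 of these. The rank-sum test called 100% of genes changed by -4, 94% of those changed by -2 and 3 of 283 unchanged genes. In these counts all hgRNAs of a gene had the same effect, and unchanged hgRNAs had the expectation of intergenic pairs. Differences between guides, shared guides and effects of breaks were not simulated, so these rates do not show how the test behaves on real data. For Torin1, limma called 92% and 84% of genes changed by 2 and by -2, 22% and 14.3% of those changed by 1 and by -1, and 6 of 3753 unchanged genes. Both simulated arms had the spread of untreated cultures (common dispersion in edgeR 0.3283), below that of Torin1 cultures (0.5413). These rates thus describe less noisy data than the real comparison. The planned tests of HAP1 against RPE1 and of paralog pairs called too many unchanged items, so their total counts are given with those of an added test. The added test over hgRNAs called 31.5% and 27.7% of genes that differed by 2 and by -2, and the simulated additive reference 24.4% (effects drawn per gene) and 4.79% (drawn per guide) of pairs with a score of -3, so both miss many differences of that size.

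In the Torin1 comparison the letters pair the cultures: residuals of cultures with the same letter correlated at 0.101, 0.151 and 0.145 over genes, and others between -0.119 and -0.0224. The fit with a replicate block stands with the alternatives. Thioguanine and thymidine libraries left most intergenic pairs at 0 (57.4% to 96.4% of them), while untreated libraries had a median of 168 to 335 counts per intergenic pair. Shares of counts in single libraries carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.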

Results

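The data were guide-pair counts from pooled CRISPR screens in which each cell carried a hybrid guide RNA (hgRNA), a single transcript that is processed into a Cas9 guide and a Cas12a guide. The 14 samples were screens in 4 cell lines: HAP1, a near-haploid human line derived from chronic myeloid leukaemia, RPE1, an immortalised human retinal epithelial line, CGR8, a mouse embryonic stem cell line, and N2A, a mouse neuroblastoma line. Each sample held 3 replicate cultures (A, B and C) from one infection, sampled at several time points or, in the thioguanine and thymidine samples, once at the end of selection, with 1 library at the start (T0) for each untreated screen. Cas12a came from Lachnospiraceae (LbCas12a) or from Acidaminococcus (AsCas12a). The human optimization library (92227 hgRNAs used) was screened in HAP1 with each Cas12a, without drug, under 6-thioguanine and under a thymidine block, which made 6 samples. The mouse optimization library (92901 hgRNAs) gave 4 samples, CGR8 and N2A with each Cas12a. The dual-targeting and paralog library (92746 hgRNAs) gave 3 samples, untreated HAP1, HAP1 under the mTOR inhibitor Torin1, and RPE1, all with LbCas12a. The exon deletion library (91948 hgRNAs) gave 1 sample, RPE1 with LbCas12a.

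Depth varied between samples and, under thymidine with LbCas12a, between replicates. Untreated optimization libraries in HAP1 held 22.9 to 33.7 M counts per library with LbCas12a and 20 to 42.0 M with AsCas12a. Thioguanine libraries held 0.733 to 1.11 M with LbCas12a and 0.946 to 1.12 M with AsCas12a. Thymidine libraries held 0.754 to 33.6 M with LbCas12a and 0.896 to 1.11 M with AsCas12a. Mouse libraries ranged from 7.79 to 32.9 M (CGR8, LbCas12a), 22.8 to 60.6 M (CGR8, AsCas12a), 15.0 to 37.4 M (N2A, LbCas12a) and 11.8 to 70.8 M (N2A, AsCas12a). Dual-targeting libraries held 7.77 to 15.6 M in untreated HAP1, 9.48 to 23 M under Torin1 and 9.07 to 14.3 M in RPE1, and exon deletion libraries 9.8 to 26.6 M. Unless stated otherwise, values are log2 fold changes against T0 after subtraction of the median of hgRNAs with both guides at intergenic sites, given as mean ± SD of the 3 replicate cultures, at time point T18 for HAP1, CGR8 and N2A and at T24 for RPE1. Adjusted p-values of genes and exons in the dropout and drug comparisons came from two-sided exact rank-sum tests against those intergenic pairs. These tests took each hgRNA as independent, so p-values of exons whose flanking pairs share guides may be too small. Values from limma and pair scores were taken without subtraction of the intergenic median.

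The human optimization library was used to compare how well each nuclease removed fitness genes when only 1 guide of the pair lay in an exon. With LbCas12a, Cas12a guides against RPL11, a protein of the large ribosomal subunit, reached -4.92 ± 0.31 (adjusted p = 3.51e-07) and those against CDK9, the kinase that releases paused RNA polymerase II, -4.27 ± 0.40 (adjusted p = 4.31e-08). The replication licensing factor MCM3 stood at -3.67 ± 0.79 (adjusted p = 7.29e-17), the isoleucyl-tRNA synthetase IARS at -2.81 ± 0.15 (adjusted p = 1.52e-20) and the spliceosome protein PLRG1 at -2.25 ± 0.13 (adjusted p = 1.71e-16). In the same screen, Cas9 guides against SPC24, a kinetochore protein, reached -5.85 ± 1.11 (adjusted p = 2.36e-07) and those against the proteasome subunit PSMB7 -5.38 ± 0.96 (adjusted p = 2.54e-12). Of 525 genes tested with Cas12a guides, 423 fell and 0 rose, and of 483 tested with Cas9 guides, 392 fell and 1 rose, the RNA helicase gene DDX17 (0.36 ± 0.11, adjusted p = 0.0184, and 0.408 at time point T12).

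Genes of several complexes needed by dividing cells were lowered with LbCas12a. Cas12a guides lowered 14 of 16 proteasome genes, 25 of 28 spliceosome genes, 14 of 15 tRNA synthetase genes, 14 of 14 DNA replication genes, 7 of 7 genes of the CCT chaperonin and 12 of 20 genes of the cytosolic ribosome, with the same counts when adjusted over the list alone. Cas9 guides lowered 14 of 14 proteasome genes, 25 of 26 spliceosome genes, 13 of 15 tRNA synthetase genes, 5 of 5 CCT genes but only 3 of 12 cytosolic ribosome genes, again the same when adjusted over the list alone. The median hgRNA with a Cas9 guide in an exon stood at -2.53 ± 0.12 and that with a Cas12a guide in an exon at -1.58 ± 0.04. Guide pairs that flank an exon lowered 1257 of 2391 exons and raised 144. They included an exon of PPIB, a peptidyl-prolyl isomerase of the endoplasmic reticulum, on chromosome 15 at 64160103 to 64160197 (-2.43 ± 0.05, adjusted p = 1.8e-23), and an exon of SNRPD3, a core spliceosomal protein, on chromosome 22 at 24567983 to 24568176 (-2.29 ± 0.32, adjusted p = 9.1e-26). The deletion median was -0.29 and that of pairs with 1 guide beside the exon and the other intergenic was -0.15. At the level of single hgRNAs, edgeR called 1385 lower and 8 higher (adjusted p under 0.05), and 673 lower and 111 higher when library factors were taken over all hgRNAs.

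With AsCas12a, Cas12a guides depleted fewer genes in HAP1. RPL11 reached -4.32 ± 0.83 (adjusted p = 5.66e-06), POLR1B, the second largest subunit of RNA polymerase I, -2.69 ± 0.32 (adjusted p = 7.36e-09) and the splicing factor SF3B3 -2.53 ± 0.28 (adjusted p = 5.31e-08). Of 518 genes tested with Cas12a guides 199 fell and 0 rose, whereas 374 of 478 genes tested with Cas9 guides fell and 3 rose, DDX17, MAGED1 and KIF1A, none of them under every alternative. Cas12a guides lowered 7 of 15 proteasome genes, 10 of 27 spliceosome genes, 9 of 15 tRNA synthetase genes, 8 of 14 DNA replication genes and 4 of 6 CCT genes (7, 10, 11, 9 and 5 adjusted over the list alone). Exon deletions lowered 797 of 2385 exons and raised 131, with the PPIB exon at -2.84 ± 0.48 (adjusted p = 1.68e-16). edgeR called 578 hgRNAs lower and 3 higher (347 and 17 with factors over all hgRNAs, 861 to 981 and 18 to 28 when 1 culture was left out).

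Compared directly over 516 genes, Cas12a guides had a median of -1.69 with LbCas12a and of -0.60 with AsCas12a. The mean difference was -0.997 ± 0.038 (SE over genes), 462 genes were lower with LbCas12a, and the sign-flip permutation p was 1e-05, the smallest that 100000 permutations can give. The replicate medians of both enzymes did not overlap (-1.58 ± 0.04 against -0.57 ± 0.02, exact permutation p = 0.1, the smallest that 3 against 3 allows). Cas9 guides in the same cells differed by -0.09 ± 0.03 over 475 genes (permutation p = 0.00367, exact p over replicates 0.8), and that difference was 0.01 (permutation p = 0.845) with a minimum of 100 counts at T0 and 0.01 without LbCas12a replicate C. Each enzyme had its own cell line and infection, so enzyme and infection cannot be told apart.

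**Figure D1:**
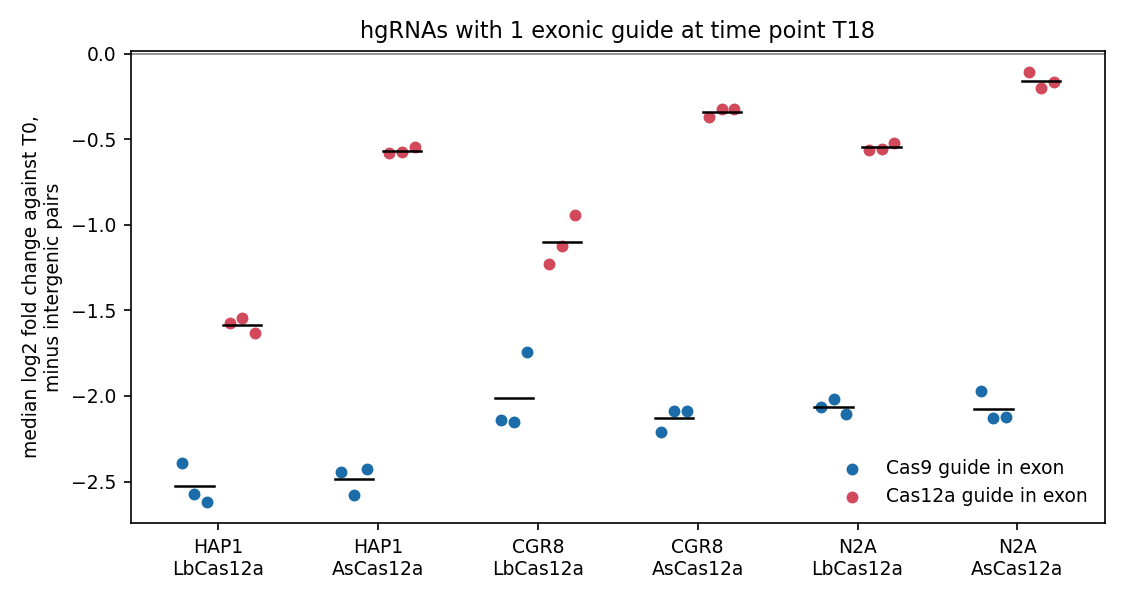
Median log2 fold change against T0 of hgRNAs with 1 exonic guide, minus that of intergenic pairs, at T18 in HAP1, CGR8 and N2A with each Cas12a. Points are replicate cultures and bars their means. Cas12a guides lay at -1.58 with LbCas12a and -0.57 with AsCas12a in HAP1, and Cas9 guides lay near or below -2 in all screens.

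The mouse library asked the same of mouse cells. In CGR8 with LbCas12a, Cas12a guides against Rpl4, a ribosomal protein, reached -2.86 ± 0.73 (adjusted p = 3.68e-10), those against Hcfc1, a transcriptional cofactor needed for cell cycle progression, -2.66 ± 0.36 (adjusted p = 4.55e-26) and those against Top2a, the topoisomerase that untangles chromosomes before mitosis, -2.56 ± 0.16 (adjusted p = 4.73e-21). In N2A, Rpl4 stood at -3.33 ± 0.41 (adjusted p = 5.69e-11) and Hcfc1 at -3.23 ± 0.28 (adjusted p = 2.66e-12). With AsCas12a, Hcfc1 fell to -2.13 ± 0.31 in CGR8 (adjusted p = 6.88e-18) and to -1.49 ± 0.49 in N2A (adjusted p = 2.75e-05), where the nuclear export receptor Xpo1 reached -2.01 ± 0.68 (adjusted p = 0.000182). In CGR8, 362 of 459 genes fell and 2 rose with LbCas12a, and 176 of 470 fell and 0 rose with AsCas12a. In N2A, 205 of 466 fell and 1 rose with LbCas12a, and 8 of 464 fell and 0 rose with AsCas12a (4 fell without replicate B, 16 with no minimum count at T0).

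Counts of proteasome genes differed between these screens, which was not tested. Cas12a guides lowered 16 of 17 with LbCas12a in CGR8, 7 of 17 with AsCas12a in CGR8, 8 of 17 with LbCas12a in N2A and 0 of 17 with AsCas12a in N2A (16, 8, 8 and 1 adjusted over the list alone). Genes of the tRNA synthetases gave 12, 6, 9 and 0 of 12 in the same screens (12, 7, 9 and 0 adjusted over the list alone). Cas9 guides lowered 15 of 16 proteasome genes and 12 of 12 tRNA synthetase genes in every mouse screen, also when adjusted over the list alone. Examples were the splicing regulator Srsf1 in CGR8 (-3.97 ± 0.40 with LbCas12a, -4.57 ± 0.40 with AsCas12a) and the mitotic kinase Wee1 in N2A with LbCas12a (-5.03 ± 0.32, adjusted p = 2.8e-12). Cas9 guides lowered 368 of 518 genes and raised 5 (CGR8, LbCas12a), 378 and 5 of 542 (CGR8, AsCas12a), 360 and 4 of 535 (N2A, LbCas12a), and 372 and 3 of 530 (N2A, AsCas12a). Exon deletions lowered 1374 of 2165 and raised 56 (CGR8, LbCas12a), lowered 1155 and raised 58 of 2166 (CGR8, AsCas12a), lowered 925 and raised 91 of 2166 (N2A, LbCas12a), and lowered 581 and raised 163 of 2166 (N2A, AsCas12a). In both optimization libraries exons were tested against intergenic pairs only, not against hgRNAs with 1 guide beside the exon. Loss of an exon and breaks beside it were thus not separated there. An exon of the ribosomal protein gene Rpl14 on chromosome 9 at 120572767 to 120572862 (genome build not given in the sources used here) reached -1.79 ± 0.62 in CGR8 with LbCas12a (adjusted p = 1.19e-37). edgeR called 3361 hgRNAs lower and 5 higher (CGR8, LbCas12a), 2356 and 29 (CGR8, AsCas12a), 1919 and 2 (N2A, LbCas12a), and 1060 and 0 (N2A, AsCas12a), and with factors over all hgRNAs 2296 and 69, 1786 and 119, 1481 and 62, and 936 and 2 in the same order.

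A direct comparison of the Cas12a enzymes in mouse cells was added after the data had been seen. LbCas12a values were lower by a mean of -0.71 ± 0.03 (SE) over 459 genes in CGR8 and -0.51 ± 0.03 over 460 genes in N2A, each with a permutation p of 1e-05, the smallest that the permutations can give, and an exact p over replicates of 0.1, the smallest that 3 against 3 allows. Cas9 guides differed by 0.14 ± 0.02 in CGR8 (0.02 without LbCas12a replicate C) and by -0.09 ± 0.03 in N2A (-0.02 without AsCas12a replicate A). Exact permutation p-values over replicates were 0.6 in CGR8 and 0.8 in N2A.

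6-Thioguanine kills cells that express HPRT1, the purine salvage enzyme that activates it. HPRT1 hgRNAs made up 78.4% ± 0.152 of all counts after selection with LbCas12a and 74.2% ± 1.88 with AsCas12a (SD, n = 3), against 0.984% ± 0.0111 and 0.945% ± 0.019 in untreated cultures at T18. Relative to those untreated cultures, Cas9 guides in HPRT1 exons rose to 16.80 ± 1.80 with LbCas12a (adjusted p = 5.63e-17) and 19.07 ± 0.16 with AsCas12a (adjusted p = 2.6e-06). Exonic Cas12a guides stood at 15.23 ± 0.99 with LbCas12a (adjusted p = 2.26e-09) and at 1.32 ± 0.23 with AsCas12a (adjusted p = 0.0739), although their share of counts was alike, 8.89% ± 1.80 and 8.46% ± 2.51. Pairs that flank the HPRT1 exon on chromosome X at 134475180 to 134475364 reached 12.05 ± 0.18 with LbCas12a (adjusted p = 7.06e-223) and 1.07 ± 0.79 with AsCas12a (adjusted p = 3.68e-84).

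Genes other than HPRT1 also lay above intergenic pairs under thioguanine relative to untreated cultures, 246 of them with Cas9 guides and LbCas12a. Of these, 243 were fitness genes lowered without drug at T18, and 0 lay above intergenic pairs when selected cultures were set against T0, where HPRT1 remained at 16.52 (adjusted p = 6.47e-15). Of the intergenic pairs, 93.9% to 96.4% had 0 counts in the selected libraries, so the size of each log2 value under the drug depends on the prior count of 2. In total, 247 genes with Cas9 guides were higher and 2 lower with LbCas12a (281 and 0 with AsCas12a), 193 genes with Cas12a guides were higher and 0 lower with LbCas12a (0 and 0 with AsCas12a, 58 genes in all with DESeq2), and 238 exons were higher and 46 lower with LbCas12a (83 and 28 with AsCas12a). Against T0 these totals were 2, 1 and 48 with LbCas12a and 1, 0 and 26 with AsCas12a. edgeR called 384 hgRNAs higher and 9408 lower with LbCas12a, and 66 and 2450 with AsCas12a, and it called 0 against T0 or with a replicate block with either enzyme. Without thioguanine replicate C it called 565 higher and 327 lower with LbCas12a, and 5 and 0 with AsCas12a.

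Thymidine arrests cells that can phosphorylate it through thymidine kinase, encoded by TK1. TK1 hgRNAs made up 37.8% ± 3.72 of counts after the block with LbCas12a and 23.8% ± 8.62 with AsCas12a (SD, n = 3), against 0.308% ± 0.0064 and 0.294% ± 0.0051 in untreated cultures at T18. Relative to those untreated cultures, Cas9 guides in TK1 rose to 13.95 ± 0.54 with LbCas12a (adjusted p = 1.9e-12) and to 14.06 ± 1.25 with AsCas12a (adjusted p = 7.14e-14). Pairs that flank the TK1 exon on chromosome 17 at 78182588 to 78182682 reached 10.64 ± 0.62 with LbCas12a (adjusted p = 1.12e-143) and 4.28 ± 0.39 with AsCas12a (adjusted p = 7.1e-36). Of the intergenic pairs, 57.4% to 71% had 0 counts after the block, so the sizes of these values and of those that follow depend on the prior count of 2.

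Few other genes rose under thymidine relative to untreated cultures at T18. TRRAP, a scaffold of histone acetyltransferase complexes, reached 8.40 ± 1.62 with Cas9 guides (adjusted p = 0.00985) and 8.28 ± 1.59 with Cas12a guides (adjusted p = 2.26e-06) with LbCas12a. Deletion of its exon on chromosome 7 at 98881089 to 98881250 gave 8.15 ± 1.09 with LbCas12a (adjusted p = 3.08e-18) and 4.92 ± 0.33 with AsCas12a (adjusted p = 5.9e-11). OGT, the O-linked N-acetylglucosamine transferase, rose with Cas12a guides to 7.27 ± 1.60 with LbCas12a (adjusted p = 0.000277) and 6.32 ± 2.18 with AsCas12a (adjusted p = 1.64e-05). The maintenance DNA methyltransferase DNMT1 rose with Cas12a guides and LbCas12a (4.48 ± 1.16, adjusted p = 0.0117) and with Cas9 guides and AsCas12a (5.646 ± 1.499, adjusted p = 0.00462), and the nuclear matrix protein MATR3 with Cas12a guides and LbCas12a (3.59 ± 2.00, adjusted p = 0.0117). The calls of TRRAP with Cas9 guides, of DNMT1 and of MATR3 ended when 1 thymidine culture was left out (adjusted p between 0.0516 and 0.991). In total 2 genes with Cas9 guides and 5 with Cas12a guides were higher with LbCas12a, and 2 and 1 with AsCas12a, TK1 included where it passed, with 0 lower. Deletions raised 18 exons and lowered 11 with LbCas12a and raised 12 and lowered 2 with AsCas12a. edgeR called 216 hgRNAs higher and 26604 lower with LbCas12a, and 90 and 21862 with AsCas12a, but with a replicate block 79 and 0 with LbCas12a and 0 and 0 with AsCas12a, and 0 with AsCas12a when any 1 untreated culture was left out. Against T0, where dropout counts too, 209 genes with Cas9 guides, 126 with Cas12a guides and 264 exons passed with LbCas12a, and 202, 8 and 116 with AsCas12a. No time point was given for either selection. Most treated libraries were shallower than untreated ones, but thymidine replicate C with LbCas12a, at 33.6 M counts, had 66.68% of hgRNAs at 0, near the 67.23% and 70.92% of the other 2 replicates.

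**Figure D2:**
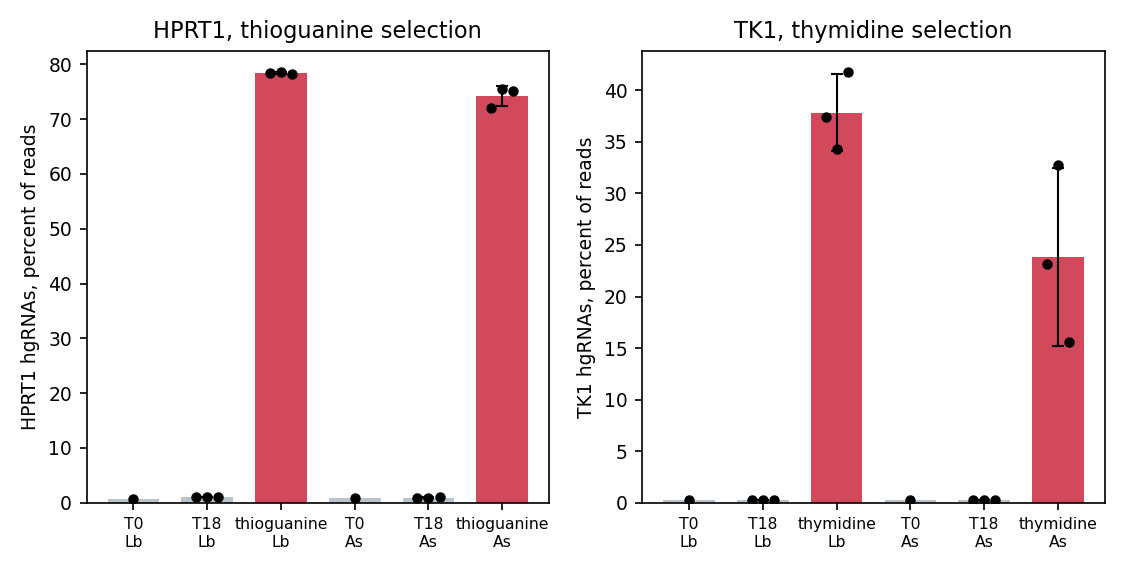
Percent of counts held by HPRT1 hgRNAs (left) and TK1 hgRNAs (right) at T0, at T18 without drug and after selection, with LbCas12a (Lb) and AsCas12a (As). Bars are means, points are libraries and error bars the SD of 3 replicate cultures. HPRT1 reached 78.4% and TK1 37.8% with LbCas12a.

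The second human library placed both guides of a pair in 1 gene. In HAP1, pairs against NAA10, the catalytic subunit of the major N-terminal acetyltransferase, reached -7.33 ± 0.85 (adjusted p = 3.71e-12) and those against the telomere protein TERF2 -7.15 ± 0.37 (adjusted p = 1.22e-16). INPPL1, an inositol phosphatase, rose to 1.68 ± 0.40 (adjusted p = 7.11e-10), as did the histone methyltransferase gene DOT1L (1.28 ± 0.18). In RPE1, the ribosomal protein RPL9 reached -6.24 ± 0.42 (adjusted p = 1.72e-16) and the sliding clamp PCNA -5.999 ± 0.385. Genes with the largest rises there included TAOK1 (5.11 ± 0.02, adjusted p = 1.72e-16) and NF2 (4.32 ± 0.94, adjusted p = 7.48e-11) of the Hippo pathway, PDCD10 (5.13 ± 0.34, adjusted p = 1.11e-13), KEAP1, the adaptor that degrades NRF2 (4.86 ± 0.23, adjusted p = 1.97e-11), TSC2 (3.08 ± 0.47) and the RAS inhibitor NF1 (2.00 ± 0.35).

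Of 3995 genes with dual-targeting pairs in HAP1, 1939 fell and 74 rose, and of 4195 in RPE1, 2299 fell and 62 rose. All 21 proteasome genes and all 26 cytosolic ribosome genes tested fell in HAP1, and 27 of 28 and 30 of 30 fell in RPE1, the same when adjusted over the list alone. Genes of respiratory complex I fell in 14 of 15 cases in HAP1 and 10 of 17 in RPE1, and genes of mitochondrial translation in 40 of 41 and 26 of 38, also when adjusted over the list alone. Of 15 listed growth suppressors, 6 fell and 1 rose in HAP1, and 1 fell and 8 rose in RPE1, also when adjusted over the list alone. Of 5 p53 pathway genes tested in RPE1, 2 rose (2 adjusted over the list alone), the p53 activators USP28 (1.43 ± 0.06, adjusted p = 4.62e-05) and CHEK2 (0.83 ± 0.14). With 1 guide in the gene, 1412 of 3728 genes fell and 34 rose in HAP1, and 989 of 4050 fell and 30 rose in RPE1. A minimum of 100 counts at T0 left 650 and 357 genes called with both or 1 guide in HAP1, and 1017 and 330 in RPE1, out of fewer genes tested. edgeR called 3843 hgRNAs lower and 48 higher in HAP1 (1777 and 387 with factors over all hgRNAs, 370 in all without replicate B) and 3283 and 334 in RPE1 (762 and 376 with factors over all hgRNAs, 2174 to 7150 in all when 1 culture was left out).

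Pairs with both guides in a gene were more depleted than pairs with 1. Over 286 genes of 10 complexes fixed beforehand, HAP1 pairs with both guides in the gene averaged -4.61 ± 0.17 and pairs with 1 guide -2.91 ± 0.09, a mean difference of -1.70 ± 0.07 (SE over genes) with 259 genes lower. In RPE1, over 300 genes, the averages were -3.72 ± 0.17 and -2.06 ± 0.12, a difference of -1.66 ± 0.06 with 283 genes lower. Genes of the tRNA synthetases showed differences of -1.93 ± 0.22 in HAP1 and -2.12 ± 0.23 in RPE1, and those of the cytosolic ribosome -1.46 ± 0.18 and -1.66 ± 0.15 (SE over genes). Both permutation p-values were 1e-05, the smallest that the permutations can give. Against single Cas9 guides alone the difference was -1.56 in HAP1 (213 genes) and -0.81 in RPE1 (246 genes), and against single Cas12a guides alone -1.77 (267 genes) and -2.17 (291 genes).

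**Figure D3:**
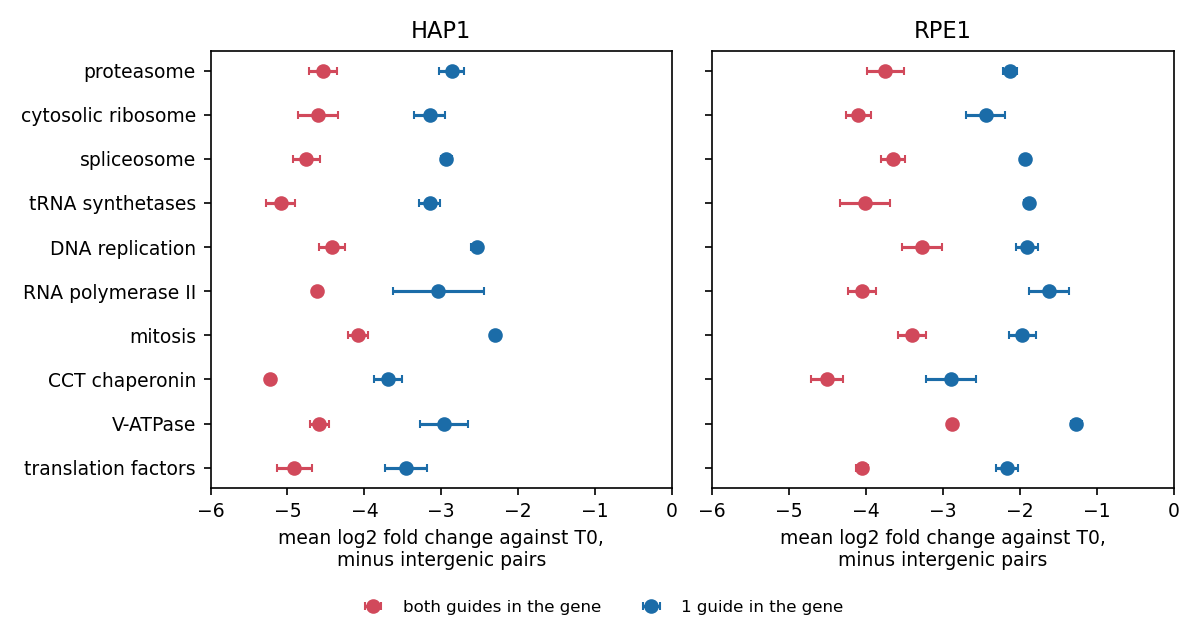
Mean log2 fold change against T0, minus intergenic pairs, of genes in 10 complexes with both guides in the gene (red) or 1 guide (blue), in HAP1 at T18 and RPE1 at T24. Points are means of 3 replicate cultures and error bars their SD. In both lines the tRNA synthetases differed by about -1.93 and -2.12.

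HAP1 and RPE1 were then compared gene by gene. KEAP1 was lower in HAP1 by -7.25 ± 0.51 (SE, limma adjusted p = 1.96e-05), NF2 by -6.58 ± 0.47, TSC2 by -6.57 ± 0.51, TAOK1 by -5.76 ± 0.26 and the pyrimidine synthesis enzyme CAD by -5.69 ± 0.30. Genes lower in RPE1 included the Hippo pathway transcription factor TEAD1 (3.92 ± 0.27), TBL1XR1, a subunit of the nuclear receptor corepressor complex (3.94 ± 0.26, limma adjusted p = 1.5e-05), the transcription factor CREB1 (3.86 ± 0.24) and the deubiquitinase USP7 (3.68 ± 0.21). All 37 mitochondrial translation genes tested were lower in HAP1 (37 adjusted over the list alone), such as MRPL20 (-4.42 ± 0.29) and MRPL4 (-4.13 ± 0.25), as were 14 of 15 complex I genes (14 adjusted over the list alone), such as NDUFA10 (-4.93) and NDUFB10 (-4.73). Of 14 listed growth suppressors 10 were lower in HAP1 and 1 higher (10 and 1 adjusted over the list alone), and 9 and 0 in the test over hgRNAs (10 and 1 adjusted over the list alone), and of 8 V-ATPase genes 8 were lower (8 adjusted over the list alone).

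Of 3870 genes, limma called 715 higher and 962 lower in HAP1. Over 5 simulated screens pooled, with 18548 unchanged genes, this test called too freely, with 33.4% of unchanged genes at p under 0.05 and 85.9% of its calls false. A moderated test over the hgRNAs of a gene, chosen after the data had been seen, gave 5.32% and 3.05%, and called 264 genes higher and 575 lower, of which 264 and 569 were also called by limma. Few genes were changed in the simulated screens, so the shares of 85.9% and 3.05% do not carry over to the real calls. Of unchanged genes, limma called 19.8% and the test over hgRNAs 0.0216%. All 37 mitochondrial translation genes, 13 complex I genes and 6 V-ATPase genes passed both tests. Line, infection and the media, which differ per the labels' protocols, cannot be told apart.

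**Figure D4:**
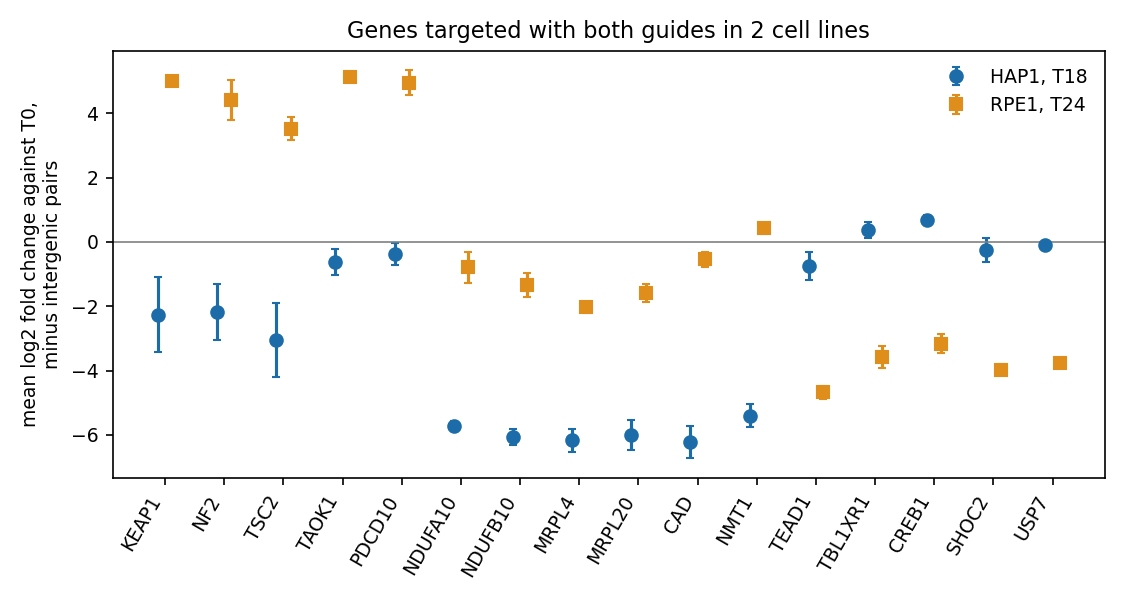
Mean log2 fold change against T0 of 16 genes targeted with both guides in HAP1 (T18, circles) and RPE1 (T24, squares). Library factors came from intergenic pairs, but their median was not subtracted, although the axis label names that subtraction. Points are means over a gene's hgRNAs and error bars the SD of 3 replicate cultures. The difference was -7.25 for KEAP1 and 3.92 for TEAD1.

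Torin1 inhibits both mTOR complexes, and HAP1 cultures were grown with it at a dose that lowered growth by 60% per the labels' protocols. Values of genes are Torin1 minus untreated cultures at T18, not against T0. A gene that rose may thus still have fallen against T0. Among the largest changes at T18 were 3 subunits of Polycomb repressive complex 2, which was not tested as a group: EED at 7.81 ± 0.43 (SE, limma adjusted p = 0.000112), EZH2 at 7.17 ± 0.42 and SUZ12 at 7.16 ± 0.57 (limma adjusted p = 0.000261), followed by the accessory subunit MTF2 at 5.36 ± 0.48. STK11, the kinase that activates AMPK, stood at 4.93 ± 0.60 (limma adjusted p = 0.00152). Losses that sensitised cells included the SAGA subunits USP22 (-2.93 ± 0.35, limma adjusted p = 0.0014) and TAF5L (-2.88 ± 0.31), and ARID2 (-2.74 ± 0.33) and PBRM1 (-2.44 ± 0.30) of a SWI/SNF complex.

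Of 15 complex I genes 5 rose (8 adjusted over the list alone), such as NDUFB10 (2.91 ± 0.30, limma adjusted p = 0.000713) and NDUFAF4 (2.90). Of 8 inhibitors of mTORC1 2 rose, STK11 and TSC2 (2.06 ± 0.53, limma adjusted p = 0.0495), with 2 adjusted over the list alone. The TSC2 call also ended with a replicate block (limma adjusted p = 0.0552) and with library factors over all hgRNAs (0.0666). Of 8 SWI/SNF genes 2 fell (4 adjusted over the list alone), and of 15 growth suppressors 4 rose and 1 fell (5 and 2 adjusted over the list alone), among them the cell cycle inhibitors CDKN1B (1.88) and RB1 (1.35) and the Hippo kinase LATS1 (-1.65). Of 17 activators of mTORC1 1 fell (1 adjusted over the list alone), the GATOR2 subunit MIOS (-1.62, limma adjusted p = 0.0198), which did not pass the test over hgRNAs (adjusted p = 0.0665) and was -0.44 by edgeR on counts summed per gene (adjusted p = 0.571). The calls of TSC2, CDKN1B, RB1 and MIOS ended without 1 or more of the cultures (limma adjusted p between 0.0538 and 0.129). Of 3956 genes limma called 256 higher and 67 lower, and the test over hgRNAs 267 and 80, with 204 and 53 in common. With a replicate block limma called 232 higher and 64 lower. Between 189 and 275 genes were called when 1 culture was left out, 161 with a minimum of 100 counts at T0, and 632 by edgeR on counts summed per gene. edgeR called 1060 hgRNAs higher and 39 lower, between 478 and 1357 in all when 1 culture was left out.

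Pairs with guides in 2 paralogs measured genetic interactions, as the departure of the pair from the sum of its single losses. In HAP1, negative scores were found for CNOT7:CNOT8, the catalytic subunits of the main deadenylase (-2.83 ± 0.35, SE over Cas9 guides), LDHA:LDHB, the lactate dehydrogenase subunits (-2.20 ± 0.28), the ubiquitin ligase scaffolds CUL4A:CUL4B (-2.88 ± 0.37), and the vesicle transport GTPases RAB1A:RAB1B (-2.83 ± 0.36), SAR1A:SAR1B (-2.89 ± 0.39) and ARF4:ARF5 (-3.42 ± 0.52), as well as the clathrin adaptor pair AP2A1:AP2A2 (-2.54 ± 0.37). Their adjusted p from limma's moderated test lay between 0.00239 and 0.0107, and against simulated additive screens between 0.0133 and 0.031. Positive scores included HSF1:HSF4 (4.00 ± 0.39) and HEATR5A:HEATR5B (3.65 ± 0.38). In RPE1, ROCK1:ROCK2, kinases of the actomyosin cytoskeleton, had -2.66 ± 0.39, with an observed pair value of 1.58 against an expected 4.24, and PI4K2A:PI4K2B, kinases of phosphatidylinositol, had 4.11 ± 0.40.

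Of 643 pairs in HAP1 the planned moderated test called 33 negative and 21 positive, and of 654 in RPE1 26 negative and 38 positive. On simulated additive screens it gave p under 0.05 for 18% to 18.9% of unchanged pairs, and 44.5% to 51.1% of its calls were false. Few pairs were changed in these screens, so the share of false calls does not carry over to the real calls. A reference drawn from simulated additive screens, chosen after the data had been seen, gave p under 0.05 for 5.31% and 5.16% of unchanged pairs. It came from the same simulation model as the screens it was tried on, so these rates do not show how it behaves on real data. It called 7 negative and 7 positive in HAP1 and 2 negative and 3 positive in RPE1, the pairs named above included. With no minimum count at T0, CNOT7:CNOT8 (-1.23), ARF4:ARF5 (-0.72), HSF1:HSF4 (1.29) and HEATR5A:HEATR5B (0.80) in HAP1 and PI4K2A:PI4K2B (0.70) in RPE1 no longer passed the planned test (adjusted p between 0.0685 and 0.549). Library factors over all hgRNAs turned the planned counts to 216 negative and 15 positive in HAP1 and to 221 and 13 in RPE1. Of 34 listed paralog pairs tested, 10 were negative and 1 positive in HAP1 (16 and 1 adjusted over the list alone) and 7 and 1 in RPE1 (10 and 5 adjusted over the list alone), whereas the simulated reference called 5 and 0 in HAP1 (10 and 1 adjusted over the list alone) and 1 and 0 in RPE1 (1 and 0 adjusted over the list alone). Of 636 pairs scored in both lines, the planned test called 7 negative in both and 2 positive in both, where 1.3 and 0.975 would be shared by chance, and this test called too freely on the simulated screens.

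Interactions were also compared between lines and under Torin1. EHBP1:EHBP1L1, adaptors of endocytic recycling, was more negative in HAP1 than in RPE1 (-2.10 ± 0.27, adjusted p = 0.04 against the simulated reference). Under Torin1, HEATR5A:HEATR5B was more negative than in untreated HAP1 (-4.18 ± 0.40, adjusted p = 0.01 against the simulated reference), and the phosphoinositide 3-kinase pair PIK3CB:PIK3CD (3.38 ± 0.40) and NFKBID:NFKBIZ (1.86 ± 0.25) were more positive. HEATR5A:HEATR5B had one of the positive scores named above in those same untreated cultures, so these results are not independent. Scores under Torin1 alone were not computed, so this difference does not show a negative score under the drug. The planned test called 32 pairs more positive and 26 more negative between lines (0 and 1 against the simulated reference), and 6 and 8 under Torin1 (2 and 1 against the simulated reference). With no minimum count at T0 the planned test called 7 pairs between lines and 0 under Torin1, and none of the 4 pairs named here passed, with HEATR5A:HEATR5B at 0.11 under Torin1.

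The exon deletion library asked which alternative exons RPE1 cells need. Deletion of an exon of PDPR, a regulator of pyruvate dehydrogenase phosphatase, on chromosome 16 at 70153391 to 70153573 (GRCh38) reached -2.97 ± 0.27 (adjusted p = 8.85e-16), that of an exon of the p53 inhibitor MDM4 -1.89 ± 0.35 (adjusted p = 0.00031) and that of an exon of MAX, the partner of MYC, -1.84 ± 0.36 (adjusted p = 1.69e-06). Exons of the p53 activators CHEK2 (0.82 ± 0.17, adjusted p = 0.018) and USP28 (0.71 ± 0.13, adjusted p = 0.00197) were higher. Cas9 guides in exons lowered the clamp loader subunit RFC5 (-5.25 ± 0.40, adjusted p = 5.65e-05) and MDM4 (-4.33 ± 1.07, adjusted p = 2.06e-05) and raised ARNT, the partner of hypoxia factors (3.21 ± 0.26, adjusted p = 2.82e-06), and AXIN1, a scaffold of the beta-catenin destruction complex (2.28 ± 0.47, adjusted p = 7.38e-06).

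Of 2130 exons tested 600 were lower and 16 higher than intergenic pairs. Among 13 exons of mitosis genes 8 were lower (11 adjusted over the list alone), including those of CENPK (-1.14 ± 0.10) and AURKA (-1.11 ± 0.38), and of 4 exons of p53 pathway genes 1 was lower and 2 higher (1 and 2 adjusted over the list alone). Set against hgRNAs with 1 guide beside the same exon and the other intergenic, 2 exons were lower and 0 higher (170 and 25 at an unadjusted p under 0.05), those of PDPR (-1.87, adjusted p = 0.0118) and of DNMT3B, a de novo DNA methyltransferase, on chromosome 20 at 32786502 to 32786627 (-1.06, adjusted p = 0.0203). Against that background the exons of CENPK (-0.30) and AURKA (-0.08) lost most of their change (adjusted p = 0.692 and 0.902), while those of MDM4 (-1.27), MAX (-1.72), CHEK2 (0.67) and USP28 (0.66) kept most of theirs without passing (adjusted p between 0.384 and 0.47). Exons of genes that Cas9 guides lowered were called in 113 of 294 cases (38.4%), and exons of other tested genes in 183 of 774 (23.6%, two-sided Fisher's exact p = 2.7e-06). Exons with a length divisible by 3 were called in 408 of 1565 cases (26.1%) and others in 192 of 565 (34%, two-sided Fisher's exact p = 0.00039). Of 880 genes with Cas9 guides 229 fell and 5 rose, and 69 genes passed in all with a minimum of 100 counts at T0 and 358 with none. edgeR called 3753 hgRNAs lower and 1914 higher (1834 and 4702 with factors over all hgRNAs, 9646 in all without replicate B).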

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

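The tests on the number of genomic breaks and all counts of other splits of the cultures were chosen after their results were seen, as were the moderated test over hgRNAs and the simulated additive reference. The comparison of Cas12a enzymes in HAP1 differed between groups, with LbCas12a lower by -0.997 over genes. HAP1 and RPE1 differed at 839 genes in the moderated test over hgRNAs and at 1 paralog pair against the simulated additive reference. Under Torin1 at time point T29, a time point that no comparison used, single hgRNAs took large shares of the counts: 15.75% for an EZH2 pair in replicate A (95% Wilson interval 15.72 to 15.77), 46.75% for a GSK3B pair in replicate B (46.72 to 46.78) and 42.45% for a Cas12a guide against GSK3B in replicate C (42.42 to 42.48), whereas their highest shares at T18 were 0.1993% under Torin1 and 0.0017% in untreated cultures.

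The first pattern is that 600 exons lay below intergenic pairs in the RPE1 exon deletion screen. If breaks beside the exon, without its loss, lowered counts, hgRNAs with 1 guide beside the exon should also be lower at these exons, and they were, by -0.22 (medians of -0.40 and -0.18, permutation p = 1e-05, the smallest that the permutations can give). A single guide beside the exon may itself harm the exon or its gene, which predicts the same shift. This result thus does not separate breaks from loss of the exon. If loss of an exon of a gene needed for growth were behind the calls, deletion minus single-guide values should be lower in genes that Cas9 guides lowered, and the difference was -0.01 (permutation p = 0.765, bootstrap interval -0.13 to 0.1), which leaves this open. Exons of genes that Cas9 guides lowered were called in 38.4% of cases, those of other tested genes in 23.6% (two-sided Fisher's exact p = 2.7e-06). Exons of a length not divisible by 3 were called in 34% of cases, others in 26.1% (two-sided Fisher's exact p = 0.00039). Both differences go with loss of the exon, although breaks that harm the gene were not separated from it. Part of the 600 calls may reflect the breaks, and 2 exons, of PDPR and DNMT3B, remained below their own single-guide background. Whether the guides match other sites of the genome was not checked. At an unadjusted rank-sum p under 0.05, 170 exons lay below that background and 25 above it. The median of deletion hgRNAs at the called exons was -0.79, but the exons were called on these same values.

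The second pattern is that fitness genes lay above intergenic pairs under thioguanine when compared with untreated cultures. A floor of the treated counts predicts that such calls vanish against T0, where dropout does not enter the reference, and 0 of 246 genes other than HPRT1 were called there. Survival of cells that lost these genes predicts calls against T0 as well, and in that same comparison 0 of 246 were found, which argues against it. In the selected libraries with LbCas12a, 97.8% to 98.9% of hgRNAs of the called genes had 0 counts, against 93.9% to 96.4% of intergenic pairs. These values also argue against survival. The floor may thus account for these calls, while HPRT1 itself stood at 16.52 against T0.

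The third pattern is that pairs with no target in the genome lay above intergenic pairs, by 0.76 ± 0.11 in HAP1 and 0.74 ± 0.05 in RPE1. If the number of genomic breaks mattered, hgRNAs with 1 targeting guide should lie between, and they did in every replicate of both lines, at 0.40 ± 0.03 in HAP1 and 0.43 ± 0.03 in RPE1 (mean of both 0.41). Those whose Cas9 guide had the target stood at 0.24 and 0.23 and those whose Cas12a guide had it at 0.62 and 0.57 (HAP1 and RPE1), so the position differed with the nuclease. A difference in T0 abundance is argued against, because matching on T0 counts left a difference of at least 0.78 in both lines. Breaks are a candidate explanation, and no biological explanation was tested.

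The 6 cultures of each comparison make 10 splits, too few for a share under 0.05, and in each case only 1 of the 10, the real one, reached the real count. Torin1 gave 323 genes (highest other split 0), HAP1 against RPE1 1677 (0), pair scores between lines 58 (24) and pair scores under Torin1 14 (13). For hgRNAs the counts were 9792 (2304) under thioguanine with LbCas12a, 2516 (2286) with AsCas12a, 26820 (0) under thymidine with LbCas12a and 21952 (0) with AsCas12a. The slope of depletion on deletion length belongs to the part on other observations.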

How the results depend on the processing

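Of 661 alternatives to 64 summary results, 518 left the result alike (counts within 1.5 times, other values on the same side of the threshold), and 25 results were alike under every alternative, among them the Cas12a comparisons and dual against single targeting. For the values that follow the cause was not tested, except that higher T0 minimums leave fewer items to test and left-out cultures fewer samples. All settings against T0 for drugs, at T18 for both lines, over hgRNAs and against the simulated additive reference were chosen after seeing the data.

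Counts of hgRNAs moved with the library factors. With TMM over all hgRNAs and with DESeq2 size factors they were 784 and 785 for human LbCas12a (1393 as reported), 364 and 360 for AsCas12a (581), 2164 and 2162 for dual HAP1 (3891), 1138 and 1141 for dual RPE1 (3617), 17917 and 26837 for thioguanine with LbCas12a (9792), and 11079 and 21749 with AsCas12a (2516). The DESeq2 Wald test gave 3888 for human LbCas12a, 2213 for CGR8 LbCas12a (3366), 7481 for dual HAP1, 6335 for dual RPE1, 9182 for thioguanine with AsCas12a, 33470 for thymidine with AsCas12a (21952) and 2788 for Torin1 (1099). Earlier time points gave 2768 for human LbCas12a, 1429 for AsCas12a, 7605 for dual HAP1 and 8310 for dual RPE1. Leaving out 1 culture gave 879 to 1009 for human AsCas12a, 370 to 5316 for dual HAP1, 2174 to 7150 for dual RPE1, 3931 to 9646 for exon deletion (5667), 892 to 10018 for thioguanine with LbCas12a, 5 to 3383 with AsCas12a, 14449 to 35975 for thymidine with LbCas12a (26820), 0 to 27803 with AsCas12a and 478 to 1357 for Torin1. Against T0 each of the 4 drug comparisons gave 0 hgRNAs.

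With a replicate block, thioguanine gave 0 hgRNAs with LbCas12a and 0 with AsCas12a, and thymidine 79 and 0, and genes with Cas9 guides under thymidine were 5 with LbCas12a and 5 with AsCas12a (2 and 2 as reported). In drug comparisons, correlations of cultures with the same letter were at or below 0.045, and under thymidine those were all above 0 and those of other letters all below, a weak pairing.

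For genes and exons, thioguanine against T0 gave 1 gene with Cas12a guides (193), 2 with Cas9 guides (249) and 48 exons (284) with LbCas12a, and 1 gene with Cas9 guides (281) and 26 exons (111) with AsCas12a. Thymidine against T0 gave 126 (5), 209 (2) and 264 (29) with LbCas12a and 8 (1), 202 (2) and 116 (14) with AsCas12a. Thioguanine with AsCas12a and Cas12a guides, 0 as reported, gave 2 with TMM, 21 with DESeq2 size factors, 58 with DESeq2 and 0 to 21 with a culture left out. DESeq2 gave 753 and 569 exons under thioguanine with LbCas12a and AsCas12a, and 4 genes with Cas9 guides under thymidine with either enzyme. A T0 minimum of 100 gave 58 exons under thioguanine with AsCas12a, and 1 and 5 genes with Cas9 guides under thymidine. Leaving out 1 culture gave 272 to 492 and 88 to 244 exons under thioguanine, and under thymidine 3 to 5 genes with Cas12a guides, 1 to 3 with Cas9 guides and 13 to 30 exons with LbCas12a, and 1 to 4 genes with Cas9 guides and 9 to 17 exons with AsCas12a. N2A with AsCas12a and Cas12a guides gave 16 genes with no T0 minimum and 4 to 12 with a culture left out (8).

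A T0 minimum of 100 gave 650 and 357 genes in dual HAP1 with both or 1 guide (2013 and 1446), 1017 and 330 in dual RPE1 (2361 and 1019), 69 genes with Cas9 guides in the exon library (234, and 358 with no minimum), 161 under Torin1 (323) and 634 between lines (1677). The own single-guide background gave 2 exons (616). Torin1 gave 632 with edgeR on summed counts and 189 to 275 with a culture left out, and HAP1 against RPE1 gave 839 over hgRNAs, and 950 over hgRNAs with both lines at T18.

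Pair scores gave, for HAP1, RPE1, their difference and Torin1 (54, 64, 58 and 14), 14, 5, 1 and 3 against the simulated additive reference, 195, 178, 137 and 130 by rank-sum, and 82, 147, 35 and 2 by limma over replicate scores. TMM over all hgRNAs gave 231 and 234 for HAP1 and RPE1, expectations from gene means 121, 113 and 88 for HAP1, the difference and Torin1, no T0 minimum 37, 7 and 0 for RPE1, the difference and Torin1, and a minimum of 100 41 and 23 for RPE1 and Torin1. Leaving out 1 culture gave 27 to 60 for HAP1 and 8 to 22 for Torin1.

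Of the small Cas9 differences between enzymes only the human one turned: -0.09 became 0.01 with a T0 minimum of 100, and -0.22 to 0.01 with a culture left out, CGR8 0.14 ranged from 0.02 to 0.22 and N2A -0.09 from -0.14 to -0.02 (-0.05 with a minimum of 100).

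For the 117 genes, exons and pairs named in the text, 1191 of 1245 alternatives were alike, 52 ended a call, 1 added one (HPRT1 with Cas12a guides and AsCas12a) and 1 turned the direction: HEATR5A:HEATR5B under Torin1, -4.18 as reported, was 0.11 with no T0 minimum, where hgRNAs with few counts at T0 enter.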

Other observations

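The test of exons on the X chromosome was chosen after the result was seen, and that of slopes on deletion length before its result was seen. In HAP1, deletions of exons on the X chromosome lay above intergenic pairs more often than others. With LbCas12a 41 of 97 exons on the X chromosome were called higher (42.27%), against 4.49% of other exons and 16.33% on chromosome 13, the next highest, and these calls fell in 26 of 40 X-linked genes. With AsCas12a 36 of 97 were called higher (37.11% against 4.15%). Medians over genes were 0.24 for 40 X-linked genes and -0.30 for 925 others with LbCas12a, and 0.23 and -0.18 with AsCas12a, each with a permutation p of 1e-05, the smallest that the permutations can give (adjusted p = 3e-05 over 6 screens). Among the 30 X-linked and 547 other genes not called lower with Cas9 guides, the medians were 0.31 and -0.21 with LbCas12a. Most of these genes had no test with Cas9 guides, so they may include fitness genes. In CGR8, X-linked exons were called higher in 11.43% of cases against 2.29% with LbCas12a (two-sided Fisher's exact p = 0.000327) and 7.14% against 2.53% with AsCas12a (p = 0.0371), and in N2A in 7.14% against 4.1% (p = 0.215) and 8.57% against 7.49% (p = 0.647). In N2A other chromosomes stood higher, chromosome 14 at 14.08% with LbCas12a and chromosome 10 at 33.77% with AsCas12a. In mouse cells the medians of X-linked and other genes were -0.06 and -0.16 in CGR8 with LbCas12a (permutation p = 0.0531), and p-values in the other screens were 0.651, 0.656 and 0.734. In CGR8 with AsCas12a these medians were -0.14 and -0.12. X-linked exons were also called lower, 14 of 97 in HAP1 with LbCas12a and 5 of 97 with AsCas12a. In CGR8 36 and 41 of 70 were called lower with LbCas12a and AsCas12a, and in N2A 26 and 13 of 70. Exons of one gene are not independent.

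The distance between guides was tested as well. For 735 Cas9 guides in 99 genes with LbCas12a, the mean slope of the log2 fold change per log10 of deletion length was 0.00445 ± 0.019 (SE, permutation p = 0.818), so that the hypothesis of deeper depletion with longer deletions was left open there. The slope was -0.0382 in N2A with LbCas12a (adjusted p = 0.0274 over 6 screens), and in the other screens it did not pass.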
